A study of Mus musculus with 8 samples.

How the data were processed

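The samples were 8 RNA-seq libraries of RAW264.7 cells, 4 from cells kept for 3 days with HA/Mg scaffolds and 4 from cells kept with TABS. Groups and replicate numbers were taken from the sample titles. The table's columns carry library names with the letter H or L, which the sample descriptions tie to TABS and HA/Mg. What the letters stand for is not given in the sources used here. An H can also be read as HA, so an exchange of the groups, which would reverse every direction, was not ruled out. Per the labels' protocols, total RNA was extracted with TRIzol and had an RNA integrity number above 7, libraries were made with the NEBNext Ultra RNA kit, and 150-base paired-end reads were produced on a NovaSeq instrument. Per the submitters' processing notes, fastp, STAR and DESeq2 were used with the mouse genome build GRCm38. The versions, the order of these steps, the tool that made the FPKM values, the gene annotation and any use of strand in counting are not given in the sources used here.

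The authors deposited 1 table of FPKM values (fragments scaled to transcript length and to the number of mapped fragments) for 55335 Ensembl gene identifiers in the 8 libraries, and no counts were used here. Of these identifiers 55154 matched the GENCODE annotation of GRCm38 used here, which gave symbols, positions, exon overlaps, the length of the longest transcript and its GC content. Because FPKM divides by length and by a total for each library, a rise in a few abundant transcripts lowers all other values, and a difference between libraries in how well transcripts of high GC content or great length are recovered is not removed.

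Sequencing depth was estimated from the spacing of low values. If whole fragments were counted, 1 fragment was worth 0.0424 to 0.0507 FPKM for each kilobase of transcript, which implies 19700000 to 23600000 fragments per library. The values used were those of genes with 1 annotated transcript. Only 33.6% to 35.5% of these low values were whole numbers of fragments within 0.05 fragment, so these depths are estimates and no count test was run. At 1 FPKM a transcript of 2 kb would hold 39.5 to 47.2 fragments, a counting error of 14.6% to 15.9%, which covers counting error only.

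The design, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Differences between TABS and HA/Mg were tested with limma 3.58.1 in R 4.3.3, as a linear model with empirical Bayes moderation and a mean-variance trend on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment. Genes at 1 FPKM or more in at least 4 of the 8 libraries entered, 10161 in all, and a gene counted as changed at an adjusted p under 0.05. Log2 changes are TABS minus HA/Mg on the log2(FPKM + 1) scale, where a change of at least 1 counted as 2-fold and which understates the change of low genes, and their errors are standard errors of the model. Gene lists with at least 5 tested members were compared with all other genes by limma's camera with an inter-gene correlation of 0.01, again with the correlation estimated for each list, and by fry. Library measures were compared by an exact two-sided permutation test over the 70 assignments of 4 against 4.

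The lists, 49 in all, covered macrophage activation, interferon, chemokines and their receptors, NF-kB, toll-like receptors, the inflammasome, bone-acting factors, matrix and adhesion, osteoclasts, antigen presentation, and lipid and energy metabolism. They also covered the cell cycle, cell death, stress responses, metals, lysosome, autophagy, phagocytosis, immediate early genes, complement, ribosomal proteins, histones and markers of 8 cell types. Named genes were the 10 largest changes in each direction among changed genes with a mean of at least 5 FPKM in the higher group and no overlap between groups. To these were added 20 genes fixed by name and up to 4 changed members of each list with the largest change (or the 2 smallest p-values where none had changed). Genes outside this rule are said to have been named after their values were seen.

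Alternatives were other pseudocounts (0.1 and 0.5), other filters on low values, rescaling to equal sums, median-of-ratios scaling, quantile normalization, and removal of abundant gene classes. Others were robust moderation, no mean-variance trend, array weights, the replicate number as a block, and each library left out in turn. Removal of each library's trends on transcript length and GC content (natural splines with 4 degrees of freedom) and a restriction to protein-coding genes were added after the data were seen. The steps were tested on simulated data made from these libraries for the comparison of TABS with HA/Mg over 10161 genes, with 50 genes changed at each size. The test recovered 50% of genes changed by 0.3 on the log2 scale and 92% of those changed by 0.5. It recovered 100% of those changed by 1 or 2, with 9 false calls among 180. The simulated noise was drawn independently for each gene and library. It held no variation shared between genes and no library set apart from its group, so these rates need not hold for the real libraries. A simulated GC trend alone, linear and equal in all libraries of a group, gave 4869 calls, and 0 limma calls once the trend was removed. It was steeper than the real difference between the groups, which was 0.159 on the log2 scale per 10 points of GC content. These 2 numbers therefore do not carry over to the real libraries. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.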

Results

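RNA was sequenced from RAW264.7 cells, a macrophage-like line derived from a mouse tumour and often used to study inflammation and osteoclast formation. The cells had been kept for 3 days with 1 of 2 bone scaffold materials, either hydroxyapatite doped with magnesium ions (HA/Mg) or the Trio-Active bone scaffold (TABS). Each material had 4 libraries, numbered as replicates 5 to 8 in both groups. Neither the components that give TABS its name nor cells grown without a scaffold are described in the labels used here, so every value below compares TABS with HA/Mg. Groups follow the sample titles, while the library names mark TABS with the letter H and HA/Mg with L, and an exchange of the groups would reverse every direction below. The deposited table gave FPKM values (fragments scaled to transcript length and to the number of mapped fragments) for 55335 genes. Each library had 9908 to 10280 genes at 1 FPKM or more, and the steps between low values implied 19700000 to 23600000 fragments per library. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

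The 2 groups separated along the first principal component of log2(FPKM + 1) over the 10161 genes tested, which held 40.2% of the variance. TABS libraries lay at 5.72 to 16.5 and HA/Mg replicates 5, 7 and 8 at -12.7, -12.7 and -16.4, while HA/Mg replicate 6 lay at 2.62, nearer to TABS. The component differed between the groups with an exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries can give, and an adjusted p = 0.0571 over the 4 library trends examined. The second component, with 18.3% of the variance, placed TABS replicates 5 and 6 at 11.6 and 11.2 and TABS replicates 7 and 8 at -8.38 and -1.70.

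**Figure D1:**
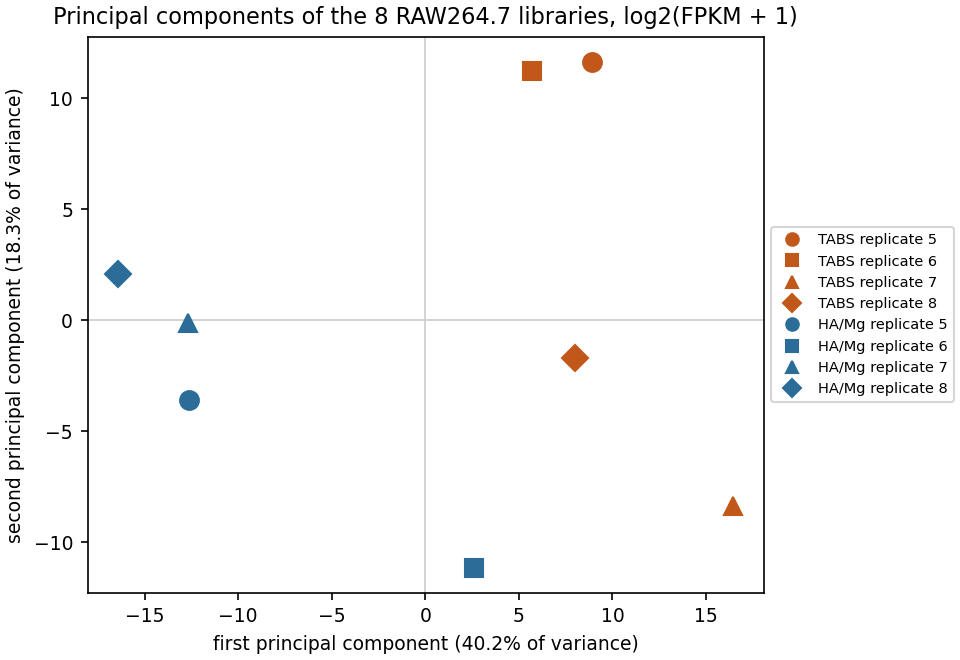
Scores of the 8 libraries on the first 2 principal components of log2(FPKM + 1), in log2 units, with 1 labelled point per library and colour for the scaffold. HA/Mg replicate 6 sits at 2.62 on the first component, between the other HA/Mg libraries (-16.4 to -12.7) and the TABS libraries (5.72 to 16.5).

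Higher in cells kept with TABS than in cells kept with HA/Mg were 7 of 9 tested chemokine genes, 13 of 29 interferon-stimulated genes, 6 of 24 NF-kB targets and the metallothioneins Mt1 and Mt2, while 24 of 35 genes of mitosis and the G2/M phase were lower. These 4 lists passed a test against all other genes at a preset inter-gene correlation, but not with an estimated one (adjusted p of 0.146 to 0.313). Ccl3 and Ccl4, which encode chemokines that draw in monocytes and lymphocytes, stood at 1314 ± 199 and 201 ± 64.2 FPKM with TABS against 759 ± 51.8 and 91.4 ± 13.1 FPKM with HA/Mg (mean ± SD, n = 4 each), or 1.73-fold and 2.20-fold higher. Mt2, a metal-binding metallothionein, was 1.87-fold higher (658 ± 61.8 against 351 ± 35.8 FPKM), and Isg15, a ubiquitin-like protein induced by interferon, was 1.55-fold higher (29.0 ± 3.08 against 18.7 ± 3.28 FPKM). Mki67, the gene of the proliferation marker Ki-67, was 1.60-fold lower (10.7 ± 0.777 against 17.1 ± 2.15 FPKM), and Hmmr, which encodes a spindle protein, was 1.5-fold lower (9.55 ± 1.06 against 14.4 ± 1.18 FPKM). All 6 passed the limma test at adjusted p from 0.0075 to 0.0138.

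On GRCm38, Ccl3 (ENSMUSG00000000982) lies on chromosome 11 from 83647844 to 83649355 on the minus strand, and Ccl4 (ENSMUSG00000018930) lies beside it from 83662584 to 83664683 on the plus strand. Mt2 (ENSMUSG00000031762) occupies chromosome 8 from 94172664 to 94173568 on the plus strand, and Isg15 (ENSMUSG00000035692) chromosome 4 from 156199424 to 156200818 on the minus strand. Mki67 (ENSMUSG00000031004) spans chromosome 7 from 135689784 to 135716361 on the minus strand, and Hmmr (ENSMUSG00000020330) chromosome 11 from 40701395 to 40733422 on the minus strand. Csf3 (ENSMUSG00000038067) lies on chromosome 11 from 98701263 to 98703629 on the plus strand, and Mmp9 (ENSMUSG00000017737) on chromosome 2 from 164940780 to 164955850 on the plus strand. All 8 are annotated as protein-coding, and their values are over whole genes. None of them shares exons with another gene at 1 FPKM or more in at least 4 libraries, and overlaps with genes below that level were not examined.

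**Figure D2:**
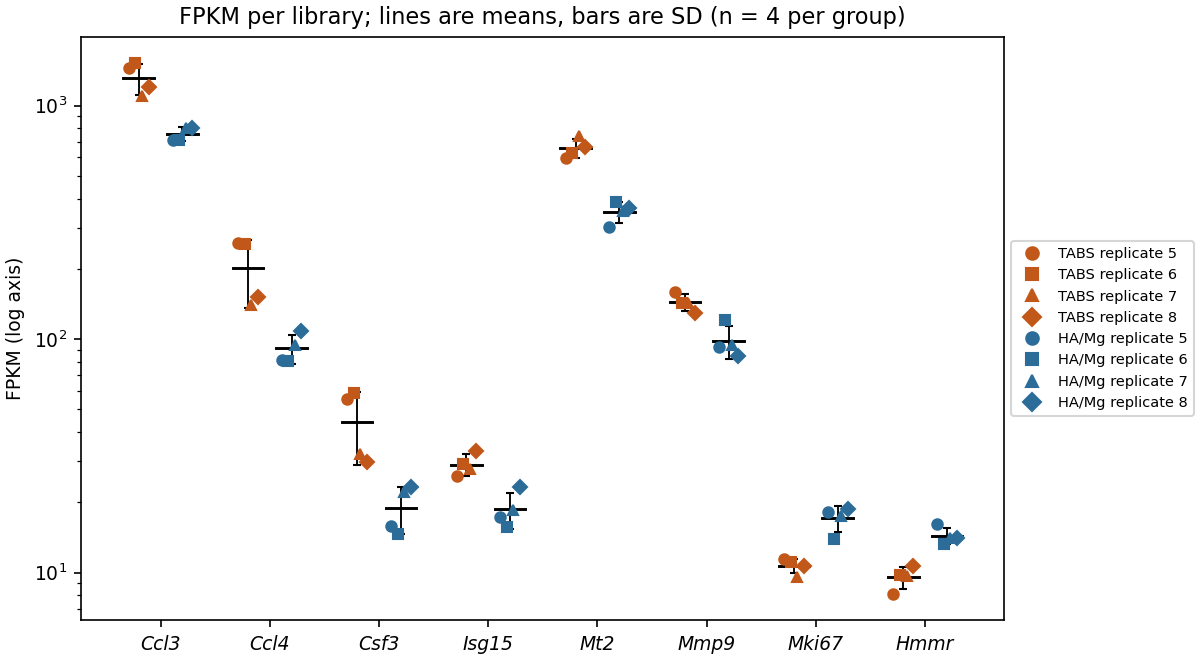
FPKM on a log axis for Ccl3, Ccl4, Csf3, Isg15, Mt2, Mmp9, Mki67 and Hmmr in each library, with 1 point per library, bars for the mean of the 4 libraries of a scaffold and error bars for the SD. Ccl3 stood at 1314 FPKM with TABS and 759 FPKM with HA/Mg, and Mki67 at 10.7 and 17.1 FPKM.

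Of the 10161 genes tested, 1842 (18.1%) changed at an adjusted p under 0.05, 515 of them higher with TABS and 1327 lower. Their median absolute log2 change was 0.29, and 9 genes changed at least 2-fold on the log2(FPKM + 1) scale, 7 higher and 2 lower. The groups did not overlap for 1634 of the changed genes and for 2343 of all those tested (23.1%, where chance gives 2.86%). Leaving out 1 library moved the number of changed genes to 414 without HA/Mg replicate 5, 475 without HA/Mg replicate 7, 693 without HA/Mg replicate 8, 855 without TABS replicate 5, 935 without TABS replicate 7, 1155 without TABS replicate 6 and 3309 without HA/Mg replicate 6. The share of changed genes that were higher was 28.0% in the values as deposited (515 higher, 1327 lower). It was 43.4% with median-of-ratios scaling (806 higher, 1050 lower) and 40.3% with quantile normalization (806 higher, 1192 lower). It was 14.0% after rescaling to equal sums (251 higher, 1536 lower) and 13.6% after leaving out mitochondrial, ribosomal protein and histone genes and rescaling (269 higher, 1704 lower). With the replicate number as a block limma called 0 genes changed (smallest adjusted p 0.0589).

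Genes richer in G and C tended to be higher with TABS. Across genes, which are not independent replicates, the log2 change followed GC content with a Spearman correlation of 0.54 and transcript length with -0.31. With the genes divided into 5 equal classes by GC content, the class lowest in GC held 14 higher and 626 lower genes and the class highest in GC held 255 higher and 19 lower. When each library's trends on transcript length and GC content were removed, an alternative chosen after the data were seen, 647 genes changed (263 higher, 384 lower, or 40.6% higher). Of the 1842 genes, 514 (170 higher, 344 lower) kept their call and direction. Of the genes named below in this section, that removal ended the calls of Ddit3, Tgfb1, Osm, Traf1, Pola1, Mcm4, Hspa5, Hsp90b1, Dnaja1, mt-Nd1, mt-Nd4, Magt1, Mmgt1, Car2, Tcirg1, Ftl1, Rpl10a, Rpl19, Rps2, Cipc, Nek7, Tap1 and Cd79b (adjusted p of 0.0546 to 0.926). The log2 change moved by less than its standard error for Rpl10a (0.331 ± 0.093 before and 0.346 ± 0.092 after), Traf1 (0.689 ± 0.191 and 0.662 ± 0.182), Tgfb1 (0.252 ± 0.067 and 0.228 ± 0.076), Osm (0.550 ± 0.137 and 0.491 ± 0.134) and Ddit3 (-0.590 ± 0.173 and -0.515 ± 0.159). The same held for Cipc (1.23 ± 0.36 and 1.30 ± 0.38), Nek7 (-1.05 ± 0.26 and -0.826 ± 0.254), mt-Nd1 (-0.663 ± 0.174 and -0.517 ± 0.165), Car2 (-0.190 ± 0.056 and -0.165 ± 0.052), Tap1 (0.243 ± 0.058 and 0.203 ± 0.068) and Cd79b (0.401 ± 0.093 and 0.326 ± 0.087). Of these 11 genes Rpl10a and Cipc did not shrink, so their lost calls do not point to length or GC content. The others of the 11 shrank toward 0. The standard error does not measure the error of such a shift, so a part of length or GC content in their lost calls is neither shown nor excluded. The log2 change shrank by more than its standard error for Hspa5 (-0.350 ± 0.061 and -0.214 ± 0.085), Hsp90b1 (-0.361 ± 0.049 and -0.187 ± 0.067), Dnaja1 (-0.429 ± 0.106 and -0.210 ± 0.071), Tcirg1 (0.208 ± 0.040 and 0.130 ± 0.034), Ftl1 (0.245 ± 0.068 and 0.124 ± 0.055), Rpl19 (0.289 ± 0.069 and 0.189 ± 0.051) and Rps2 (0.232 ± 0.071 and 0.129 ± 0.059), and for Pola1, Mcm4, mt-Nd4, Magt1 and Mmgt1 as given below.

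**Figure D3:**
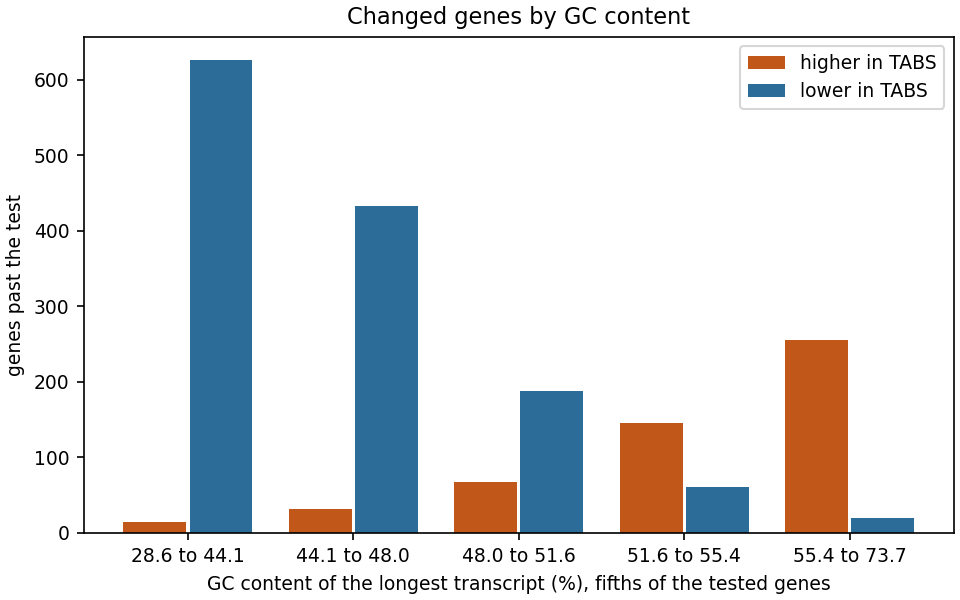
Number of genes higher and lower with TABS at an adjusted p under 0.05, as bars side by side, in each of 5 equal classes of the tested genes by GC content, in percent, of the longest annotated transcript. The class lowest in GC holds 14 higher and 626 lower genes and the class highest in GC 255 higher and 19 lower.

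Among gene lists fixed before the data were examined, 25 of the 40 with enough tested members passed limma's camera test, 20 higher with TABS and 5 lower. With an inter-gene correlation estimated for each list, 0 of 40 passed camera, 7 lay at an unadjusted p under 0.05, and 17 passed fry, which asks whether a list's genes move one way and does not compare them with other genes. Every list that passed is therefore given below with both p-values.

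Of 9 tested chemokine genes 7 rose and 2 did not pass (7 rose adjusted over the list alone), with a median log2 change of 0.47 and camera adjusted p = 1.3e-07 (adjusted p = 0.146 with an estimated correlation). Ccl4 rose by 1.08 ± 0.21 on the log2 scale (SE, adjusted p = 0.0138), and Ccl5 by 0.83 ± 0.12 (76.4 against 43.0 FPKM, adjusted p = 0.00859). Ccl3 rose by 0.78 ± 0.10 (adjusted p = 0.00851) and Ccl2 by 0.64 ± 0.11 (24.4 against 15.4 FPKM, adjusted p = 0.0112). TABS replicates 5 and 6 lay higher than TABS replicates 7 and 8: Ccl4 was 257, 255, 139 and 151 FPKM in TABS replicates 5 to 8 and 81.6, 80.7, 94.6 and 108 FPKM in HA/Mg replicates 5 to 8. After removal of the length and GC trends 7 members still rose.

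Of 12 tested M1-associated inflammatory genes 3 rose and 9 did not pass (7 rose adjusted over the list alone). Their camera adjusted p was 0.000265 (adjusted p = 0.270 with an estimated correlation). The list's median deviation was 0.28 and 0.30 in TABS replicates 5 and 6 but -0.02 and 0.05 in TABS replicates 7 and 8, against -0.27 to -0.07 with HA/Mg. In TABS replicates 5 to 8 Csf3 was 55.3, 58.9, 32.3 and 29.8 FPKM and Acod1 was 202, 215, 107 and 122 FPKM. The members that rose were Csf3, the granulocyte growth factor G-CSF (44.1 ± 15.1 against 19.0 ± 4.33 FPKM, log2 change 1.14 ± 0.24, adjusted p = 0.0170), and Acod1, the enzyme that makes itaconate (161 ± 54.9 against 78.3 ± 20.3 FPKM, log2 change 1.01 ± 0.26, adjusted p = 0.0296). Cd40, a co-stimulatory receptor, rose as well (25.7 against 19.2 FPKM, adjusted p = 0.0128). Leaving out 1 library ended the call of Csf3 (without HA/Mg replicate 5, adjusted p = 0.0577) and of Acod1 (without TABS replicate 5 or 6 or HA/Mg replicate 5 or 7, adjusted p of 0.0613 to 0.0842). Members below the threshold were Nos2, the inducible nitric oxide synthase (32.0 ± 3.97 against 26.9 ± 2.20 FPKM, adjusted p = 0.0944), and Tnf (19.7 ± 4.96 against 15.0 ± 4.03 FPKM, adjusted p = 0.219). Ptgs2, the inducible cyclooxygenase, did not pass either (27.3 ± 12.1 against 14.4 ± 1.54 FPKM, adjusted p = 0.0702). Without TABS replicate 7, Nos2 and Ptgs2 passed (adjusted p = 0.0438 and 0.0411), as did Ptgs2 after removal of the length and GC trends (adjusted p = 0.0480). Il1b (0.716 against 0.383 FPKM) and Il6 (0.747 against 0.487 FPKM) were too low to be tested.

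Of 24 tested NF-kB targets and feedback genes 6 rose and 18 did not pass (11 rose and 1 fell adjusted over the list alone), with camera adjusted p = 1.8e-05 (adjusted p = 0.313 with an estimated correlation). The list's median deviation was 0.25 and 0.19 in TABS replicates 5 and 6 but -0.01 in both TABS replicates 7 and 8, below HA/Mg replicate 8 at 0.01. The genes that rose included Bcl2a1a, an anti-apoptotic gene with near-identical copies whose reads may be shared (17.2 against 10.4 FPKM, adjusted p = 0.00851), and Nfkb2, an NF-kB subunit (63.0 against 44.2 FPKM, adjusted p = 0.0135). Traf1, a signalling adaptor, rose from 3.71 to 6.86 FPKM (adjusted p = 0.0385). The call of Traf1 ended without any 1 of TABS replicates 5 to 7 or HA/Mg replicates 5, 7 and 8 (adjusted p of 0.0548 to 0.0934). Of 19 tested chemokine and cytokine receptors 3 rose and 16 did not pass (4 rose adjusted over the list alone), with camera adjusted p = 0.00257 (adjusted p = 0.324 with an estimated correlation). Tnfrsf1b, the second TNF receptor, rose from 37.9 ± 1.19 to 62.2 ± 12.4 FPKM (adjusted p = 0.0120), and Csf1r, the receptor for the macrophage growth factor CSF1, from 96.5 ± 0.988 to 112 ± 3.72 FPKM (adjusted p = 0.0112). Of 17 tested toll-like receptor signalling genes 3 rose and 14 did not pass (4 rose adjusted over the list alone), with camera adjusted p = 0.020 (adjusted p = 0.451 with an estimated correlation). That call ended without HA/Mg replicate 6 (adjusted p = 0.0883) or TABS replicate 5 (adjusted p = 0.0637), with no filter on low values (adjusted p = 0.0503) and with array weights (adjusted p = 0.0534). The list's median deviation was 0.21 and 0.17 in TABS replicates 5 and 6 but -0.08 and -0.05 in TABS replicates 7 and 8, below HA/Mg replicates 5, 7 and 8 (-0.0008 to 0.05). Cd14, a co-receptor for bacterial lipopolysaccharide, stood at 307 against 225 FPKM (adjusted p = 0.0168, or 0.0579 without HA/Mg replicate 5).

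Of 29 tested interferon-stimulated genes 13 rose and 16 did not pass (16 rose adjusted over the list alone), 27 had a positive log2 change, and the camera adjusted p was 3.2e-09 (adjusted p = 0.152 with an estimated correlation). Isg15 rose by 0.62 ± 0.11 on the log2 scale (adjusted p = 0.0133), Zbp1, a nucleic acid sensor, from 1.65 to 2.92 FPKM (adjusted p = 0.00851) and Irf7, a transcription factor of the interferon response, from 31.2 to 45.5 FPKM (adjusted p = 0.00940). Cxcl10, an interferon-induced chemokine, was low, at 1.01 against 1.76 FPKM (adjusted p = 0.0154, or 0.0546 without HA/Mg replicate 5). After removal of the length and GC trends 16 members rose. Of 19 tested genes of MHC class I presentation 1 rose, the peptide transporter Tap1 (13.8 against 11.5 FPKM, adjusted p = 0.0245), and 18 did not pass (1 rose adjusted over the list alone). The list's camera adjusted p was 0.000431 (adjusted p = 0.247 with an estimated correlation), and HA/Mg replicate 6 had a higher median deviation (0.03) than TABS replicate 6 (0.01). Tap1 lost its call without any 1 of TABS replicates 5 and 8 or HA/Mg replicates 5, 7 and 8 (adjusted p of 0.0505 to 0.0774).

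**Figure D4:**
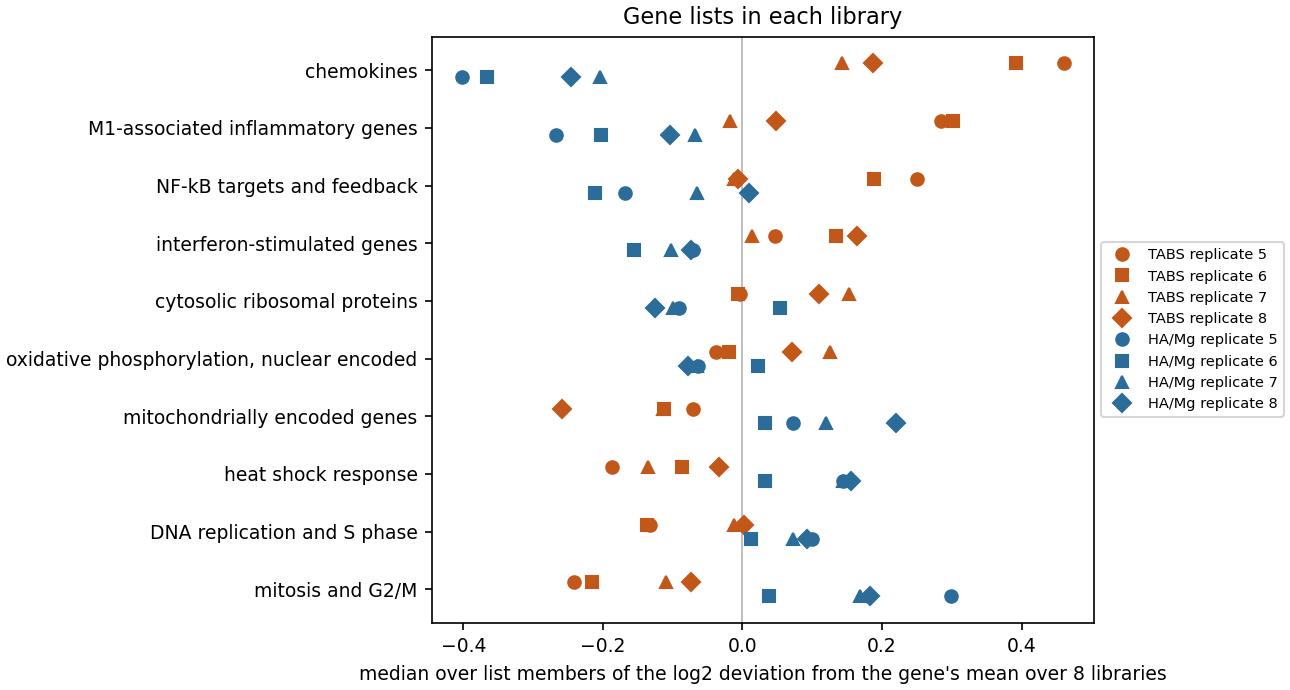
Median over each list's tested members of the log2 deviation from the mean of the 8 libraries, with 1 point per library and colour for the scaffold, for 10 gene lists. Chemokines lay at 0.14 to 0.46 in the TABS libraries and -0.40 to -0.20 in the HA/Mg libraries, and mitosis genes at -0.24 to -0.07 and 0.04 to 0.30.

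Of 35 tested genes of mitosis and the G2/M phase 24 fell and 11 did not pass (28 fell adjusted over the list alone), and 34 had a negative log2 change. Their median log2 change was -0.32 and the camera adjusted p was 7.4e-10 (adjusted p = 0.305 with an estimated correlation). Mki67 fell by 0.62 ± 0.09 on the log2 scale (adjusted p = 0.00859), Hmmr by 0.55 ± 0.08 (adjusted p = 0.00859) and Ect2, an activator of cytokinesis, by 0.53 ± 0.10 (8.91 to 5.81 FPKM, adjusted p = 0.0138). Cenpe, a kinetochore motor, stood at 2.17 against 3.80 FPKM (adjusted p = 0.0207) and lost its call without any 1 of HA/Mg replicates 5, 7 and 8 (adjusted p of 0.0550 to 0.0655). HA/Mg replicate 6 had a median deviation of 0.04 over the list, against 0.17 to 0.30 in the other HA/Mg libraries, and after removal of the length and GC trends 16 members fell. Of 35 tested genes of DNA replication and S phase 10 fell and 25 did not pass (10 fell adjusted over the list alone), with camera adjusted p = 0.00310 (adjusted p = 0.474 with an estimated correlation). The list's median deviation was -0.13 and -0.14 in TABS replicates 5 and 6 but -0.01 and 0.003 in TABS replicates 7 and 8, near HA/Mg replicate 6 at 0.01. The genes that fell included Pola1, a DNA polymerase subunit (3.54 against 4.86 FPKM, adjusted p = 0.0137, or 0.0506 without HA/Mg replicate 5). Mcm4, a subunit of the replicative helicase, fell too (33.6 against 41.5 FPKM, adjusted p = 0.0192, or 0.0536 to 0.0637 without HA/Mg replicate 5, 7 or 8). After removal of the length and GC trends 2 of the list fell, and neither gene passed, since their changes shrank from -0.371 ± 0.071 to -0.157 ± 0.054 for Pola1 (adjusted p = 0.108) and from -0.295 ± 0.065 to -0.160 ± 0.066 for Mcm4 (adjusted p = 0.157). Replication-dependent histones were too low to test as a list, with 3 tested members, none of them past limma's test.

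Of 11 tested matrix remodelling genes 4 rose and 7 did not pass (5 rose adjusted over the list alone), with camera adjusted p = 0.00800 (adjusted p = 0.305 with an estimated correlation, and 0.0534 with no filter on low values). Mmp9, a gelatinase also made by osteoclasts, rose from 98.1 ± 15.8 to 144 ± 12.2 FPKM (adjusted p = 0.0136). Plaur, the urokinase receptor, rose from 10.1 to 15.8 FPKM (adjusted p = 0.00851). Of 20 tested integrin and adhesion genes 6 rose, 2 fell and 12 did not pass (7 rose and 2 fell adjusted over the list alone), with camera adjusted p = 0.00287 (adjusted p = 0.303 with an estimated correlation). Itga5, a subunit of the fibronectin receptor, rose from 30.3 to 43.9 FPKM (adjusted p = 0.0109). Of 9 tested bone-acting, angiogenic and neurotrophic factors 3 rose and 6 did not pass (3 rose adjusted over the list alone), with camera adjusted p = 0.0152 (adjusted p = 0.247 with an estimated correlation). These were Tgfb1 (67.9 ± 4.19 against 56.9 ± 4.94 FPKM, adjusted p = 0.0335) and the related cytokines Osm (8.53 ± 2.11 against 5.40 ± 0.293 FPKM, adjusted p = 0.0282) and Lif (2.0 ± 0.854 against 0.775 ± 0.0717 FPKM, adjusted p = 0.0270). Vegfa, an angiogenic factor, stood at 5.19 ± 0.824 against 4.97 ± 0.548 FPKM (adjusted p = 0.786). Spp1, the gene of osteopontin, stood at 1817 ± 119 against 1918 ± 82.7 FPKM (adjusted p = 0.394), and Bmp2 was below the level tested. The list's call ended without TABS replicate 5, 6 or 8 (adjusted p of 0.0569 to 0.0760) and with a filter at 5 FPKM (adjusted p = 0.128). The call of Tgfb1 ended without any library but HA/Mg replicate 6 (adjusted p of 0.0525 to 0.0944). It ended for Osm without TABS replicate 5 or HA/Mg replicate 5, 7 or 8 (adjusted p of 0.0594 to 0.0777) and for Lif without HA/Mg replicate 5, 7 or 8 (adjusted p of 0.0656 to 0.0788).

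Osteoclast genes did not pass the test as a group. Of 15 tested members of the list of osteoclast differentiation and resorption 2 rose, 1 fell and 12 did not pass (2 rose and 1 fell adjusted over the list alone), with camera adjusted p = 0.33. Mmp9 and the proton pump subunit Tcirg1 (59.2 against 51.2 FPKM, adjusted p = 0.0137, or 0.0516 without HA/Mg replicate 5) rose. Car2, a carbonic anhydrase, fell from 229 to 201 FPKM (adjusted p = 0.0458) but not without any 1 of TABS replicates 5, 6 and 8 or HA/Mg replicates 5, 7 and 8 (adjusted p of 0.0817 to 0.122). Nfatc1, the main transcription factor of osteoclast formation, stood at 4.87 ± 0.269 against 5.48 ± 0.496 FPKM (adjusted p = 0.180, or 0.0355 without HA/Mg replicate 6). The osteoclast enzymes Acp5 (0.458 against 0.526 FPKM) and Ctsk (0.322 against 0.357 FPKM) were below the level tested.

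The metallothioneins Mt2 and Mt1 rose by 0.90 ± 0.09 and 0.81 ± 0.11 on the log2 scale (adjusted p = 0.00750 and 0.00851), Mt1 from 116 to 205 FPKM. The list of metallothioneins and zinc handling as a whole had 3 genes that rose, 3 that fell, among them the zinc importer Slc39a10 (4.50 against 7.07 FPKM, adjusted p = 0.0101), and 10 that did not pass. Adjusted over the list alone 3 rose and 3 fell, and the camera adjusted p was 0.583. Of 18 tested genes of magnesium transport 2 fell, Magt1 (9.51 against 11.1 FPKM, adjusted p = 0.0338) and Mmgt1 (9.49 against 12.1 FPKM, adjusted p = 0.0135), and 16 did not pass (2 fell adjusted over the list alone). The camera adjusted p was 0.509. Magt1 lost its call without any 1 of TABS replicates 5 to 7 or HA/Mg replicates 5, 7 and 8 (adjusted p of 0.0691 to 0.102), and after removal of the length and GC trends its change was 0.0095 on the log2 scale. That removal also ended the call of Mmgt1, whose change shrank from -0.317 ± 0.060 to -0.113 ± 0.040 (adjusted p = 0.114), so none of the list remained called. Trpm7, a magnesium-permeable channel, stood at 1.23 ± 0.268 against 2.25 ± 0.744 FPKM (adjusted p = 0.0602, or 0.00513 without HA/Mg replicate 6). Of 17 tested iron handling genes 4 rose and 13 did not pass (6 rose and 1 fell adjusted over the list alone), with camera adjusted p = 0.0106 (adjusted p = 0.152 with an estimated correlation, and 0.188 with quantile normalization). The ferritin chains Fth1 (1826 against 1476 FPKM, adjusted p = 0.0168) and Ftl1 (3447 against 2903 FPKM, adjusted p = 0.0380), both with processed copies that can share reads, and the metal transporter Slc11a1 (37.7 against 31.7 FPKM, adjusted p = 0.0193) were among them. Ftl1 had a log2 change of -0.034 with quantile normalization. Leaving out 1 library ended the call of Fth1 (HA/Mg replicate 5 or 7, adjusted p of 0.0587 to 0.0607), Slc11a1 (TABS replicate 5 or HA/Mg replicate 5, adjusted p = 0.0505 and 0.0526) and Ftl1 (any but HA/Mg replicate 6, adjusted p of 0.0517 to 0.112). Of 24 tested calcium and phosphate handling genes 3 rose, 1 fell and 20 did not pass (3 rose and 2 fell adjusted over the list alone), with camera adjusted p = 0.824.

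Of 12 tested heat shock genes 5 fell and 7 did not pass (6 fell adjusted over the list alone), with camera adjusted p = 0.0186 (adjusted p = 0.364 with an estimated correlation). Hspd1, the mitochondrial chaperonin, fell from 372 ± 9.38 to 293 ± 8.66 FPKM (adjusted p = 0.00851) and Hspa4 from 34.7 to 26.2 FPKM (adjusted p = 0.0114). Dnaja1, a co-chaperone, stood at 5.05 against 7.19 FPKM (adjusted p = 0.0269, or 0.0660 to 0.0831 without TABS replicate 5 or 7 or HA/Mg replicate 5, 7 or 8). Of 24 tested genes of the unfolded protein response 7 fell and 17 did not pass (7 fell adjusted over the list alone), with camera adjusted p = 0.0337 (adjusted p = 0.247 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, fell from 585 ± 44.4 to 458 ± 16.9 FPKM (adjusted p = 0.0116) and Hsp90b1 from 282 to 220 FPKM (adjusted p = 0.00851). The list's call ended with median-of-ratios scaling (adjusted p = 0.145), after removal of the length and GC trends (adjusted p = 0.0702, median change -0.10 before and -0.06 after), with array weights (adjusted p = 0.0825) and with the replicate number as a block (adjusted p = 0.0508). It also ended without HA/Mg replicate 6 (adjusted p = 0.255), TABS replicate 6 (adjusted p = 0.0794) or TABS replicate 8 (adjusted p = 0.0569). After that removal Hspa5 and Hsp90b1 stood at adjusted p = 0.145 and 0.116.

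Of 79 tested cytosolic ribosomal protein genes 75 had a positive log2 change, with a median of 0.12 and camera adjusted p = 1.1e-10 (adjusted p = 0.409 with an estimated correlation, and 0.0819 with quantile normalization). Only 3 of them rose, Rpl19 (1289 against 1057 FPKM, adjusted p = 0.0242), Rpl10a (330 against 262 FPKM, adjusted p = 0.0393) and Rps2 (395 against 336 FPKM, adjusted p = 0.04999), while 76 did not pass. The family has many processed copies that can share reads. Adjusted over the list alone 0 passed limma's test, with 27 at an unadjusted p under 0.05, and fry gave the list an adjusted p = 0.137. Each of the 3 lost its call without TABS replicate 7 or 8 or HA/Mg replicate 5, 7 or 8, and Rpl10a and Rps2 without TABS replicate 5 as well (adjusted p of 0.0529 to 0.123). HA/Mg replicate 6 had a median deviation of 0.05 over these genes, against -0.13 to -0.09 in the other HA/Mg libraries. The values were -0.003 and -0.006 in TABS replicates 5 and 6 and 0.15 and 0.11 in TABS replicates 7 and 8. After removal of the length and GC trends the list's median change was 0.096 (camera adjusted p = 1.5e-06, or 0.460 with an estimated correlation). Nuclear-encoded genes of oxidative phosphorylation had 3 of 74 that rose, 1 that fell and 70 that did not pass, with camera adjusted p = 2.0e-05 (adjusted p = 0.449 with an estimated correlation). Their median deviation was higher in HA/Mg replicate 6 (0.02) than in TABS replicates 5 and 6 (-0.04 and -0.02). Adjusted over the list alone 0 of these passed limma's test, with 13 at an unadjusted p under 0.05, and fry gave an adjusted p = 0.235. Of the 13 mitochondrially encoded genes 4 fell and 9 did not pass (4 fell adjusted over the list alone), with camera adjusted p = 0.0400 (adjusted p = 0.303 with an estimated correlation). Among them were mt-Nd4 (406 ± 22.2 against 512 ± 36.5 FPKM, adjusted p = 0.0135) and mt-Nd1 (499 ± 74.2 against 801 ± 187 FPKM, adjusted p = 0.0328). The list's call ended with median-of-ratios scaling (adjusted p = 0.0560), with the replicate number as a block (adjusted p = 0.0508) and after removal of the length and GC trends (adjusted p = 0.390, median change -0.17 before and -0.04 after), when the change of mt-Nd4 shrank from -0.333 ± 0.062 to -0.175 ± 0.065 (adjusted p = 0.125). It also ended without TABS replicate 6 (adjusted p = 0.0666), TABS replicate 8 (adjusted p = 0.1005) or HA/Mg replicate 6 (adjusted p = 0.0858). The call of mt-Nd1 ended without TABS replicate 5, 7 or 8 or HA/Mg replicate 5, 7 or 8 (adjusted p of 0.0556 to 0.0915).

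The rule for the largest changes named 10 genes in each direction. The higher ones were Nup62, Csf3, Ccl4, Acod1, Mt2, Atf3, Ccl5, Mt1, Ccl3 and Clu. Nup62, a nuclear pore protein, had the largest value (47.8 ± 19.3 against 14.7 ± 4.51 FPKM, log2 change 1.60 ± 0.31, adjusted p = 0.0140). Its annotated exons overlap those of Il4i1 on the same strand and of Atf5 on the other, genes named after their values were seen, so its reads may be shared with them. Atf3, a stress-induced transcription factor, rose from 43.0 to 79.1 FPKM (adjusted p = 0.0139) and Clu, the secreted chaperone clusterin, from 22.7 to 39.8 FPKM (adjusted p = 0.0125). The lower ones were Eif5, a translation initiation factor (5.60 against 11.1 FPKM, adjusted p = 0.00971) and Cry1, a repressor of the circadian clock (4.6 against 7.91 FPKM, adjusted p = 0.0242). In order of log2 change, Mki67 came next, then Fbxo5, an inhibitor of the anaphase-promoting complex (6.79 against 10.95 FPKM, adjusted p = 0.00859), and Rbm10, a splicing regulator (4.36 against 7.35 FPKM, adjusted p = 0.0239). Kpna2, a nuclear import receptor (36.7 against 57.4 FPKM, adjusted p = 0.0113), Spata5 (4.02 against 6.67 FPKM, adjusted p = 0.00851) and Ranbp2, a nuclear pore protein (4.25 against 7.01 FPKM, adjusted p = 0.0230) followed. The last were Ddit3, the stress-induced factor CHOP (74.8 against 110 FPKM, adjusted p = 0.0447), and Fam111a (7.53 against 11.9 FPKM, adjusted p = 0.0191). Without 1 library the adjusted p lay above 0.05 for Cry1 (TABS replicate 5 or HA/Mg replicate 5, 7 or 8, 0.0550 to 0.0742) and Ranbp2 (TABS replicate 7 or HA/Mg replicate 5, 7 or 8, 0.0522 to 0.0737). The same held for Rbm10 (TABS replicate 5, 6 or 7 or HA/Mg replicate 5 or 7, 0.0515 to 0.0721), Fam111a (TABS replicate 5 or HA/Mg replicate 5, 7 or 8, 0.0502 to 0.0639) and Ddit3 (any but TABS replicate 8, 0.0610 to 0.0980). Exons of Irf7, Csf1r, Nfkb2, Tap1, Hspd1, Hsp90b1, Dnaja1, Ftl1, Spata5, Rbm10 and Ddit3 overlap an annotated gene on the other strand, and whether the authors' counting used strand is not given in the sources used here. Those of Ftl1, Hsp90b1 and mt-Nd4 overlap an annotated gene on the same strand, so their reads may be shared as well.

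The 9 genes changed at least 2-fold on the log2(FPKM + 1) scale were Csf3, Ccl4, Acod1, Nup62 and Fen1 and, named after their values were seen, Crybg2, Cipc, Gm24044 and Nek7. Fen1 and Nek7 were the 2 lower ones. Because 1 is added to each value, changed genes at low levels can differ more than 2-fold in mean FPKM without being among these, as Lif (2.58-fold higher) and Klf2 (2.11-fold lower) did. Crybg2 stood at 4.33 to 5.15 FPKM in the TABS libraries and at 0.253 to 0.340 FPKM in HA/Mg replicates 5, 7 and 8, but at 3.41 FPKM in HA/Mg replicate 6. Gm24044 lay at 1.25 to 2.04 FPKM with TABS, at 1.41 FPKM in HA/Mg replicate 5 and at 8.2e-05 to 0.000134 FPKM in the other HA/Mg libraries. Cipc lay at 6.27 to 7.44 FPKM with TABS, at 0.915 to 1.77 FPKM in HA/Mg replicates 5, 7 and 8 and at 6.83 FPKM in HA/Mg replicate 6. Fen1, a nuclease of DNA replication, lay at 22.7 to 31.9 FPKM with HA/Mg and at 6.23 to 6.81 FPKM in TABS replicates 6 to 8, with 24.8 FPKM in TABS replicate 5. Nek7 lay at 9.46 to 10.9 FPKM with HA/Mg and 3.22 to 3.66 FPKM in TABS replicates 6 to 8, with 9.73 FPKM in TABS replicate 5. Leaving out 1 library ended the call of Crybg2 (HA/Mg replicate 5 or 7, adjusted p of 0.0556 to 0.0576), Cipc (any but HA/Mg replicate 6, 0.0752 to 0.111) and Gm24044 (TABS replicate 5, 7 or 8 or HA/Mg replicate 7 or 8, 0.0517 to 0.0718). It also ended those of Fen1 (0.0596 to 0.0753) and Nek7 (0.0620 to 0.0790), both without TABS replicate 6, 7 or 8 or HA/Mg replicate 5, 7 or 8. With no filter on low values all of the 9 but Ccl4 lost their call (adjusted p of 0.0507 to 0.131), and Cipc did with robust moderation (adjusted p = 0.0679). The number of such genes was 3 without TABS replicate 6, 4 without HA/Mg replicate 5 or 7, and 5 without TABS replicate 5 or 8 or HA/Mg replicate 8.

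Macrophage markers had the highest levels among the cell type markers. Lyz2 averaged 1333 FPKM and Cd68 494 FPKM over the 8 libraries, and 11 of 12 macrophage markers reached a mean of 1 FPKM. The highest markers of other types were Acta2 at 1.04 FPKM for osteoblast and mesenchymal cells, Eng at 0.724 FPKM for endothelium and Lck at 3.41 FPKM for T and NK cells. For the rest they were S100a8 at 0.0645 FPKM for neutrophils and mast cells, Ccr7 at 0.216 FPKM for dendritic cells and Cldn4 at 0.00314 FPKM for epithelium. Of the B cell markers Ighm stood at 123 FPKM and Blnk at 5.44 FPKM, and Cd79b rose from 2.76 to 3.94 FPKM (adjusted p = 0.0222, or 0.0520 to 0.0684 without TABS replicate 5 or 7 or HA/Mg replicate 5 or 7). Of 11 tested macrophage markers 3 rose and 8 did not pass (4 rose adjusted over the list alone), with camera adjusted p = 0.00485 (adjusted p = 0.152 with an estimated correlation). Of the 6 library measures examined, 1 lay at an unadjusted p under 0.05 in an exact two-sided permutation test. That was the share of summed FPKM in mitochondrially encoded genes (4.77 ± 0.192% with TABS against 5.38 ± 0.0106% with HA/Mg, exact p = 0.0286, adjusted p = 0.171), where the groups did not overlap (4.54% to 5.01% against 5.37% to 5.39%). This p is the smallest that 4 against 4 libraries can give, so no single measure could pass after adjustment over 6.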

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

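The tests of HA/Mg replicate 6 over inflammatory genes, of GC trends among the libraries of a group, and of ribosomal protein genes after removal of length and GC trends were chosen only after the result was seen.

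In 21 of the 240 groups of 4 libraries examined, 1 library stood apart from the other 3 by Dixon's test. Chance at 1 in 20 gives 12, which is only a rough guide. The 240 groups are not independent and include genes named after their values were seen. A group with 3 values of 0, as for Mrc1, S100a8 and Cldn4, is flagged by any value above 0. Of the 21, 10 concerned HA/Mg replicate 6. This library was the low one for Fam111a (8.76 FPKM against 12.7 to 13.1 in the other 3 HA/Mg libraries), Vegfa (4.15 against 5.14 to 5.33), Dnaja1 (5.56 against 7.70 to 7.77), and Slc39a10 (5.84 against 7.41 to 7.52). It was also the low one for Slc11a1 (29.1 against 32.3 to 32.8), Slc2a1 (51.0 against 58.7 to 60.0) and Nek7 (9.46 against 10.7 to 10.9). It was the high one for Crybg2 (3.41 against 0.253 to 0.340), Cipc (6.83 against 0.915 to 1.77) and summed FPKM (340459 against 326760 to 328513).

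The remaining cases involved single genes in other libraries. Rbm10 was 5.19 FPKM in TABS replicate 8 against 3.95 to 4.14 in the other TABS libraries, Tgfb1 was 74.2 in TABS replicate 7 against 65.6 to 66.0, Plaur was 15.0 in TABS replicate 8 against 16.0 to 16.2, and Rpsa was 1877 in TABS replicate 7 against 1621 to 1664. S100a8 was 0.1999 FPKM in TABS replicate 8 and listed at 0 in the other 3 TABS libraries. Fen1 and Nek7 were 24.8 and 9.73 FPKM in TABS replicate 5 against 6.23 to 6.81 and 3.22 to 3.66. Within HA/Mg, mt-Nd4 was 566 FPKM in replicate 8 against 486 to 497, and Gm24044 was 1.41 FPKM in replicate 5 against 8.2e-05 to 0.000134. Mrc1 was 0.00697 FPKM in HA/Mg replicate 5 and Cldn4 0.0251 FPKM in HA/Mg replicate 7, and both were listed at 0 in the other 3 HA/Mg libraries.

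HA/Mg replicate 6 lay between the groups: over the 3309 genes called without it, its median position was 0.63 (interquartile range 0.35 to 0.89) on a scale with the other HA/Mg libraries at 0 and TABS at 1, where the other 7 libraries lay at -0.12 to 0.29 from their own group. A wrong label had been set to need a position above 0.75 and to be excluded below 0.5, so this planned measure left it undecided. The chemokine, M1-associated, NF-kB and interferon-stimulated lists were pooled as inflammatory lists. Over their 30 members called without it the position was -0.020 (interquartile range -0.25 to 0.30), below all medians of random sets of 30 called genes (lowest 0.24). Over 34 ribosomal protein genes it was 0.92 (0.78 to 1.06). Among the lists outside these sets it ran from 0.16 over 5 tricarboxylic acid cycle genes to 0.98 over 5 magnesium transport genes, so low positions were not confined to inflammatory genes. Nor did all inflammatory genes lie low, since the inflammasome and pyroptosis list, which was not pooled, lay at 0.97 (0.91 to 1.04) over 5 genes. The TABS libraries differ among themselves over ribosomal protein genes (median deviation -0.006 to 0.15). A wrong label, or a share of TABS RNA, therefore need not move ribosomal protein and inflammatory genes by the same amount. Over chemokines, however, all TABS libraries lay at 0.14 to 0.46. HA/Mg replicate 6 lay at -0.37 there, within the HA/Mg range of -0.40 to -0.20. Either cause would have raised that value, so the chemokine values argue against either as the whole cause. Length and GC trends are not the whole cause either, since the position was 0.61 (0.31 to 0.86) over 1582 genes after their removal, and a difference in the culture or handling of this sample stays open as an untested hypothesis.

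The trend of log2 changes with GC content did not come from the listed pathways alone, since the Spearman correlation across genes was 0.55 over the 9307 genes in no list. A GC trend also appeared within both groups, with each library set against the others of its group. The correlation across genes was 0.259 for HA/Mg replicate 6 and -0.183, -0.242 and -0.053 for HA/Mg replicates 5, 7 and 8. For TABS replicates 5 to 8 it was 0.029, -0.220, 0.217 and -0.098. Without HA/Mg replicate 6 the correlation of the comparison between the groups was 0.52. A technical source that varies between libraries and a biological one cannot be told apart, because such a trend can follow the scaffold as well. For mitosis genes the median log2 change of -0.32 lay outside the central 95% of lists matched on length, GC content and mean expression (-0.19 to -0.03). With median-of-ratios scaling 75% of their 24 calls were kept. These values argue against length and GC content, and against scaling, as the whole cause. Matched genes were drawn independently, so the matched ranges leave out library variation shared by a list's members. The estimated inter-gene correlation of the mitosis list was 0.55, so such shared variation is not argued against. For interferon-stimulated genes and chemokines the median of 0.25 (matched lists -0.10 to 0.03) argues against length and GC content as the whole cause. Median-of-ratios scaling kept 94.7% of their 19 calls. However, it moved the median log2 change of all tested genes from -0.036 to 0.012, which favours higher calls. That share therefore decides nothing about scaling. Calls kept after rescaling to equal sums, where the median of all tested genes was -0.088, were not counted for these lists. An effect of the scaffold on these genes and on mitosis genes stays open as a hypothesis. For ribosomal protein genes the median of 0.12 lay within the range of matched lists (0.06 to 0.12), but removal of length and GC trends left a median of 0.096 and camera adjusted p = 1.5e-06 (0.460 with an estimated correlation), so such trends and other causes cannot be told apart, and 66.7% of only 3 calls kept leaves scaling undecided.

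Of the 9 genes changed at least 2-fold, 4 (Crybg2, Fen1, Gm24044 and Nup62) have exons that overlap another expressed gene, against 15.7% of tested genes (Fisher's exact p = 0.0396), which is consistent with reads shared between neighbours. The overlapping genes, named after their values were seen, were Cd52 for Crybg2 (250 against 177 FPKM, log2 change 0.49, limma adjusted p = 0.00851) and Tmem258 for Fen1 (34.5 against 31.7 FPKM, log2 change 0.11, adjusted p = 0.373). The others were Rpsa for Gm24044 (1699 against 1373 FPKM, log2 change 0.32, adjusted p = 0.0814) and Il4i1 (1.81 against 0.752 FPKM, log2 change 0.66, adjusted p = 0.0168) and Atf5 (11.7 against 10.6 FPKM, log2 change 0.13, adjusted p = 0.309) for Nup62. Cd52 and Il4i1 thus passed in the same direction as Crybg2 and Nup62. Each partner changed by less than the gene it overlaps, which speaks against a change of the partner as the source but leaves open how reads were divided between neighbours. For Cipc and Nek7, whose values fell into a high and a low set of libraries, no biological explanation was tested.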

How the results depend on the processing

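The removal of length and GC trends and the restriction to protein-coding genes were tests chosen only after the result was seen. The real split was the only 1 of the 35 splits into 4 and 4 to reach any of the 3 counts. These were 1842 changed genes (highest other split 4), 25 lists (highest other 19) and 9 genes changed at least 2-fold (highest other 1). A share of 1 in 35 is the smallest this test can give, so it argues against chance but cannot exclude it. For the lists another split came near to the real count. Leaving out 1 library gave 414 to 3309 changed genes, 3 to 10 changed at least 2-fold and 22 to 25 lists. Changed genes numbered 414, 3309, 475 and 693 without HA/Mg replicates 5 to 8 in turn and 855, 1155, 935 and 1234 without TABS replicates 5 to 8. Genes changed at least 2-fold numbered 4, 10, 4 and 5 without HA/Mg replicates 5 to 8 and 5, 3, 7 and 5 without TABS replicates 5 to 8. With all 8 libraries, changed genes numbered 808 with no filter on low values, where 22906 genes were adjusted for, 3532 with array weights and 647 with length and GC trends removed, and 1554 to 1998 under the others without a block. Genes changed at least 2-fold numbered 15 with a pseudocount of 0.1 and 1 with no filter, and 7 to 12 under the others without a block. For array weights, and for the change to 647, the cause was not tested. Lists past camera numbered 20 to 25 under all alternatives but the estimated correlation, which left 0 (7 at an unadjusted p under 0.05, and 17 by fry). Rescaling to equal sums cannot change a share of the sum, and no single library measure could pass after adjustment over 6, so that alternative says nothing about the stability of the library measures.

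With the replicate number as a block, limma called 0 genes changed (2987 at an unadjusted p under 0.05, smallest adjusted p 0.0589), 0 changed at least 2-fold and camera 23 lists. Whether equal numbers mark a pair is not given in the labels, and no pairing was seen in the values. The correlations of the deviations of same-numbered libraries were 0.01, -0.27, -0.16 and 0.13, and 1 of 8 libraries correlated best with its own number. So few libraries cannot exclude a pairing.

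Of 88 tested genes followed through the alternatives 80 had changed. Cell type markers named only for their level, and the partners Cd52, Tmem258, Rpsa, Il4i1 and Atf5 of overlapping genes, were not followed. Over all their alternatives, 1400 of 1740 values kept direction and call, 338 kept direction and lost the call, and 2 reversed: Ftl1 with quantile normalization (log2 change -0.034) and Magt1 with length and GC trends removed (0.0095). Of genes that had not changed, the sign also differed for Spp1 with length and GC trends removed (0.044) and for Vegfa without TABS replicate 6 (-0.0032) or HA/Mg replicate 6 (-0.021), over a range of -0.021 to 0.15 without 1 library. The cause was not tested. Nos2 and Hmox1, which had not changed, passed with median-of-ratios scaling (adjusted p = 0.0309 and 0.0209) and with array weights (0.0394 and 0.0223), and Ptgs2 and Trpm7 passed with array weights (0.0291 and 0.00785). With no filter on low values 35 of the 88 lost their call. The calls of 36 genes were lost only under the block or without 1 library. At the estimated depth a gene at 1 FPKM carries a counting error of 14.6% to 15.9% for a 2 kb transcript. Small changes of genes near 1 FPKM may therefore have been missed, but detection by expression level was not tested.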

Other observations

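Every list below was fixed before the data were examined, and of the tests in this part only the removal of length and GC trends was chosen after the result was seen. Of the genes named only in this part, that removal ended the calls of Axl, Nr4a1, Slc2a1, Hmgcs1 and Cd74 (adjusted p of 0.0504 to 0.218). The log2 change shrank by less than its standard error for Axl (0.318 ± 0.068 before and 0.302 ± 0.083 after), Nr4a1 (0.632 ± 0.180 and 0.553 ± 0.173) and Slc2a1 (0.360 ± 0.097 and 0.327 ± 0.083). A part of length or GC content in the lost calls of Axl, Nr4a1 and Slc2a1 is neither shown nor excluded. The change shrank by more than its standard error for Hmgcs1 (-0.468 ± 0.087 and -0.301 ± 0.079) and Cd74 (0.211 ± 0.062 and 0.110 ± 0.053).

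Of 19 tested phagocytosis and scavenger receptor genes 6 rose and 13 did not pass (8 rose adjusted over the list alone), with camera adjusted p = 0.000281 (adjusted p = 0.146 with an estimated correlation). The genes that rose included Axl, a receptor for apoptotic cells (7.09 against 5.5 FPKM, adjusted p = 0.0178), and Clec4d, a lectin receptor (69.0 against 58.4 FPKM, adjusted p = 0.0168). Another was Cd68, a lysosomal glycoprotein of macrophages (539 against 450 FPKM, adjusted p = 0.0197). Leaving out 1 library ended the call of Axl (HA/Mg replicate 5, 7 or 8, adjusted p of 0.0502 to 0.0604), Clec4d (HA/Mg replicate 5, adjusted p = 0.0540) and Cd68 (HA/Mg replicate 5, 7 or 8, adjusted p of 0.0530 to 0.0659). Of 35 tested lysosome genes 6 rose, 3 fell and 26 did not pass (10 rose and 4 fell adjusted over the list alone), with camera adjusted p = 0.00102 (adjusted p = 0.305 with an estimated correlation, and 0.132 with quantile normalization). Of 19 tested genes of lipid uptake, storage and efflux 3 rose, 1 fell and 15 did not pass (3 rose and 1 fell adjusted over the list alone), with camera adjusted p = 0.0289 (adjusted p = 0.305 with an estimated correlation, 0.0895 with quantile normalization, 0.0927 with a filter at 5 FPKM and 0.0637 without TABS replicate 5). TABS replicate 7 had a median deviation of -0.06 over this list, below all HA/Mg libraries (-0.04 to -0.008). Fabp5, a fatty acid binding protein, rose from 182 to 222 FPKM (adjusted p = 0.0147). Tgfb1 and the chemokine gene Ccl22 (10.3 against 5.76 FPKM, adjusted p = 0.00940) rose among the M2-associated genes. Of 7 tested 2 rose and 5 did not pass (4 rose adjusted over the list alone), with camera adjusted p = 0.0224 (adjusted p = 0.240 with an estimated correlation, 0.0559 with median-of-ratios scaling, 0.0922 with a mean of at least 1 FPKM and 0.0791 with no filter on low values). Tgfb1 lost its call without any library but HA/Mg replicate 6 (adjusted p of 0.0525 to 0.0944), and the M2-associated genes Arg1, Mrc1 and Il10 were below the level tested.

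Immediate early genes moved in both directions. Of 21 tested 6 rose, 3 fell and 12 did not pass (7 rose and 3 fell adjusted over the list alone), with camera adjusted p = 0.00694 (adjusted p = 0.474 with an estimated correlation, and 0.0840 after removal of length and GC trends). That removal left the list's median log2 change about as large (0.21 before and 0.24 after). The members that rose went from 6 to 1, however, and those that fell from 3 to 2. A part of length or GC content in the lost call is therefore neither shown nor excluded. Nr4a1, a nuclear receptor, rose from 2.09 to 3.93 FPKM (adjusted p = 0.0410, but 0.0530 to 0.105 without TABS replicate 5 or 6 or any 1 HA/Mg library). Klf2, a transcription factor known to restrain inflammatory genes, fell from 1.57 to 0.745 FPKM (adjusted p = 0.0122). The list's median deviation was 0.31 and 0.37 in TABS replicates 5 and 6, -0.16 and -0.01 in TABS replicates 7 and 8, and -0.23 to -0.01 in the HA/Mg libraries. Of 22 tested glycolysis genes 2 rose, 1 fell and 19 did not pass (2 rose and 1 fell adjusted over the list alone), with camera adjusted p = 0.0101 (adjusted p = 0.152 with an estimated correlation, 0.525 with quantile normalization and 0.133 after removal of length and GC trends, with a median log2 change of 0.06 before and 0.05 after). The enzyme Aldoc stood at 48.0 against 41.2 FPKM (adjusted p = 0.0170, or 0.0514 without HA/Mg replicate 7). The glucose transporter Slc2a1 stood at 74.4 against 57.4 FPKM (adjusted p = 0.0349, or 0.0645 to 0.0814 without TABS replicate 5 or 6 or HA/Mg replicate 5, 7 or 8).

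Other lists did not pass camera. Of 24 tested cholesterol biosynthesis genes 2 rose, 4 fell and 18 did not pass (adjusted p = 0.710, and 4 rose and 5 fell adjusted over the list alone). Hmgcs1, which makes the precursor of mevalonate, fell from 17.2 to 12.1 FPKM (adjusted p = 0.0133). Of 25 tested NRF2 and oxidative stress genes 4 rose, 1 fell and 20 did not pass (adjusted p = 0.109, and 4 rose and 2 fell adjusted over the list alone). Gpx1, a glutathione peroxidase, fell from 166 to 127 FPKM (adjusted p = 0.0133), and Hmox1, the heme-degrading enzyme, stood at 89.3 ± 5.19 against 74.7 ± 9.25 FPKM (adjusted p = 0.0639). Fatty acid synthesis had 3 genes that rose, 4 that fell and 8 that did not pass (adjusted p = 0.875, and 4 rose and 4 fell adjusted over the list alone). Hypoxia response had 2, 5 and 22 (adjusted p = 0.824, and 2 rose and 5 fell adjusted over the list alone). The tricarboxylic acid cycle had 1, 3 and 18 (adjusted p = 0.569, and 1 rose and 3 fell adjusted over the list alone) and the integrated stress response 2, 3 and 24 (adjusted p = 0.302, and 2 rose and 3 fell adjusted over the list alone). Apoptosis had 1, 3 and 18 (adjusted p = 0.689, and 1 rose and 3 fell adjusted over the list alone). The p53 targets had 1, 3 and 13 (adjusted p = 0.954, and 1 rose and 3 fell adjusted over the list alone) and autophagy 3, 1 and 19 (adjusted p = 0.259, and 3 rose and 1 fell adjusted over the list alone). Complement had 1 that fell and 6 that did not pass (adjusted p = 0.484, and 2 rose and 1 fell adjusted over the list alone). The inflammasome had 1 that rose, 1 that fell and 13 that did not pass (adjusted p = 0.710, with 0 of these past limma's test adjusted over the list alone). Of the MHC class II genes only 4 were tested, too few for camera, and Cd74, the invariant chain, stood at 700.5 against 606 FPKM (adjusted p = 0.0458, but 0.0845 to 0.129 without TABS replicate 5, 7 or 8 or HA/Mg replicate 5, 7 or 8). Median, mean and test differed in sign for 9 of the 40 lists, and 0 of those 9 passed camera.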
